A study of Mus musculus with 2 samples.

How the data were processed

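Dissected genital tubercles of 3 male and 3 female embryos, chosen from 2 litters, were pooled by sex after a wait of 2 hours in medium for genotyping. Per the labels' protocols, the tissue was digested with collagenase XI at 37 °C for 30 minutes, passed through a 40 µm strainer and loaded as 1 male and 1 female sample on a droplet platform with a 3' gene expression kit of version 3.1. The labels give 150 bp paired-end sequencing at a target of 25000 reads per cell. Pooling means that differences between embryos cannot be told from these libraries.

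The deposited files hold UMI counts, whole numbers per gene and barcode with no normalization, for each library. Per the submitters' processing notes and the file headers, they were made with Cell Ranger 3.1 on the mm10 build. The annotation version was not given in the sources used here. The deposited count matrices list 31053 genes and all 6794880 barcodes of the kit, so cells had not been called. Of the gene IDs, 31011 (99.9%) matched the GENCODE M21 annotation of the same build, which gave coordinates and gene types. At least 1 UMI was found at 1254850 male and 1413965 female barcodes, and 90.9% and 92.7% of UMIs lay in barcodes with at least 1000 UMIs.

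Limits, markers, gene lists, clustering settings and the rule for named genes were set before the data were examined. A cell had at least as many UMIs as the higher of 1000 and the larger of both libraries' order-of-magnitude limits (the 99th percentile of the 3000 largest barcodes divided by 10, which was 4854 for the male and 4666 for the female library), at least 500 genes and at most 10% mitochondrial UMIs. Over the limit of 4854 UMIs lay 10082 male and 11035 female barcodes. The limit on genes removed 137 and 193 of these and the mitochondrial limit 307 and 242, which left 9638 and 10600. Scrublet, in scanpy 1.11.5, marked 0% of cells at its automatic threshold in both libraries and so had not worked. As set for that case, the cells with the highest doublet scores were removed at 0.8% per 1000 cells, 743 male (7.71%) and 899 female cells (8.48%). Doublets between similar cells are not removed by this. The rate was taken from the 9638 and 10600 barcodes left, while 19799 male and 21058 female barcodes had at least 1000 UMIs. The barcode ranks did not break at the limit of 4854 UMIs. The male library had 4892 UMIs at rank 9948 and 4756 at rank 10426. It fell steeply only later, from 2937 UMIs at rank 17478 to 863 at rank 20123. With a limit of 2000 UMIs, 15587 male and 15977 female cells were kept. Many barcodes below 4854 UMIs thus passed as cells, and the rate taken without them was too low. The median mitochondrial share of the kept cells was 6.53% in both libraries.

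For clustering, counts were scaled to 10000 per cell and log-transformed. From 2000 variable genes ranked within each library, the Y-linked genes, Xist, Tsix, haemoglobin and mitochondrial genes were left out, which left 1993 genes. With 30 principal components, 15 neighbours and a Leiden resolution of 1 (python-igraph 0.11.9, seed 0), the 18596 cells fell into 23 clusters. Clusters were named from 117 marker genes of 16 classes. A name needed a mean log2 fold of at least 2 over the markers of a class against all other cells, with a pseudocount of 5 CPM, and at least 3 detected markers, and clusters of no other class with mesenchyme markers were named mesenchyme-like. This gave 8 classes, of which the mesenchyme-like class held 16 clusters and 17355 cells. No class had a cluster with more markers of another class than of its own among its 10 leading genes. Markers that define a class are not reported as results.

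Levels were UMIs summed over the cells of a class in a library, per 1000000 UMIs of that sum, for classes with at least 50 cells in each library. The male over female ratio was given an exact conditional interval for 2 Poisson counts, and shares of cells were given exact Clopper-Pearson intervals, both at 95% and both for counting error only. With 1 library per sex no test was made and no gene was called changed. A ratio against 0 counts is given as a lower bound against a floor of 3 counts, and a share of 0 as the limit that 3 counts allow. In the mesenchyme-like class the libraries held 62039670 and 76710750 UMIs, and 12803 genes reached a summed count of 100. The other classes compared held fewer UMIs, down to 946750 and 652901 in the immune-like class, and their intervals are wider.

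Genes were named by rule. In the mesenchyme-like class these were the 12 highest and 12 lowest ratios among genes with a summed count of at least 200 and at least 20 CPM in the higher library. In each other class compared they were the 5 highest and 5 lowest among genes with a summed count of at least 100 and at least 50 CPM in the higher library. Y-linked and X inactivation genes were left out of both and reported apart. Each fixed list gave up to 4 members with a summed count of at least 100 and the largest absolute ratio, all members of the first 4 lists were named, and each cluster gave up to 5 leading genes among those in at least 25% of its cells. Results of some genes that this rule names are not reported here, while counts and medians of sets include them.

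The 19 lists (260 genes, 1 absent from the files) covered steroid receptors and conversion, androgen-responsive genes of the tubercle, Y-linked genes, X inactivation and escape, Hedgehog, Wnt, FGF, BMP, Hox and limb-type patterning, retinoic acid, ephrin and cell adhesion, extracellular matrix, S phase, G2 and mitosis, immediate early and heat shock, hypoxia and glycolysis, haemoglobin, urethral epithelium and surface epithelium. The median ratio of a list was set against 10000 random lists of the same size drawn from 20 bins of mean expression, and its percentile describes these libraries only. Cells of a class were thinned to 2000 UMIs each for shares of cells with a Mki67 UMI.

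The level and list steps were tested on simulated data, drawn for the real genes from the real means and library sizes with 200 genes changed. These were independent Poisson counts, with no variation between cells or embryos and no link between genes. The intervals assume the same, so the simulation checks the calculation only and not how well the intervals suit the real counts. In the mesenchyme-like comparison (12803 genes), 95.4% of intervals of unchanged genes held the true ratio. Genes changed by a fold of 1.25 had it in 94% of intervals, and 88% of their intervals lay wholly on the right side of 0. For a fold of 2 these shares were 95% and 100%. Of 200 random lists with no change, 4% had a percentile outside the central 95%.

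Alternatives were other limits on UMIs (500, 2000 or each library's own) and on mitochondrial UMIs (5% and 20%), no doublet removal, other Leiden resolutions (0.5 and 2), 1000 or 4000 variable genes, genes centred within each library, and clustering without cell cycle genes. For levels they were TMM factors (edgeR 4.0.16) and median-of-ratios factors (DESeq2 1.42.0) in R 4.3.3, haemoglobin and mitochondrial UMIs left out of the total, subtraction of the profile of barcodes with under 100 UMIs, thinning to 2000 UMIs, the mean of cells and equal cluster weights. The share of free RNA, estimated from haemoglobin UMIs outside erythroid-like cells, was 4.36% in the male and 3.49% in the female library. Alternatives chosen after seeing the data were the removal of the 16% of cells with the highest doublet scores, the 20% mitochondrial limit for levels, the smooth muscle-like cluster counted with the mesenchyme, and clustering without the smooth muscle genes. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used for the calculations and matplotlib 3.10.9 for the figures.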

Results

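Single-cell RNA sequencing was carried out on mouse genital tubercles, the embryonic outgrowth that forms the penis or the clitoris, at embryonic day 14.5 (Theiler stage 22). Wild-type C57BL/6 embryos were sexed by genotyping and 3 embryos of each sex were pooled, so that the data hold 1 male and 1 female library, each of dissociated cells from a pool. The male library held 130105692 unique molecular identifiers (UMIs) and the female library 144515562. After limits on UMIs, genes and mitochondrial UMIs and the removal of likely doublets, 8895 male and 9701 female cells were kept, with a median of 6795 and 7123 UMIs and of 2541 and 2659 genes per cell. The kept cells held 71954335 male and 83631391 female UMIs. With 1 library per sex there was no replicate check of any difference. Every value is therefore given for both libraries, and each interval is an exact 95% interval that covers counting error only. Ratios are male over female on a log2 scale, from UMIs summed over the cells of a class and expressed as counts per 1000000 UMIs of that sum (CPM). Coordinates are those of the mm10 build.

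**Figure D1:**
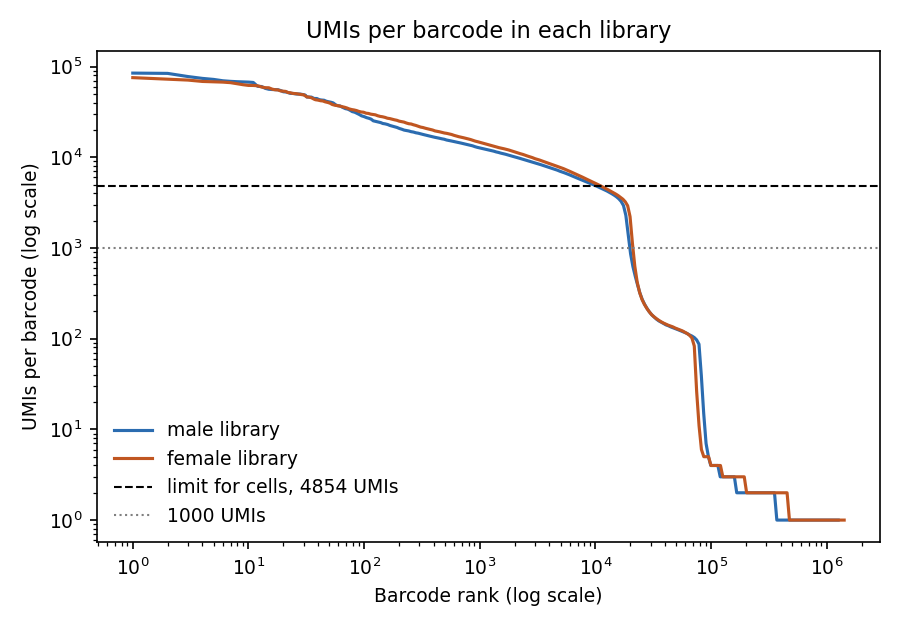
UMIs per barcode (log scale) against barcode rank (log scale) in the male and the female library, with the limit for cells of 4854 UMIs and a line at 1000 UMIs. Of the barcodes with at least 1000 UMIs, 9717 male and 10023 female barcodes lay below the limit for cells.

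The sex-linked genes separated both pools as labelled. Xist (chromosome X, positions 103460366 to 103483254), the non-coding RNA that coats the inactive X chromosome, reached 1343 CPM in the female library and 0.0834 CPM in the male library. A Xist UMI was seen in 99.03% of female cells (9607 of 9701) and in 0.0675% of male cells (6 of 8895; interval 0.0248 to 0.147%). The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty together reached 165 CPM in the male library and 0.0837 CPM in the female library. At least 1 of their UMIs was seen in 68.0% of male cells and in 0.0722% of female cells (interval 0.0290 to 0.149%). The share in the opposite sex is the background level of each measure, at median depths of 6795 and 7123 UMIs. In mesenchyme-like cells, Ddx3y, an RNA helicase gene, was at least 1517-fold higher in the male library, against a floor of 3 counts in the female library, where it had 0 counts. Eif2s3y, a translation initiation factor gene, was at least 1516-fold higher by the same floor. Kdm5d had 1518 male and 2 female counts (log2 9.87, interval 8.02 to 12.92) and Uty 1583 and 5 (log2 8.61, interval 7.39 to 10.24).

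Genes that escape X inactivation were higher in the female mesenchyme-like cells. Eif2s3x, the X-linked partner of Eif2s3y, was at 48.3 CPM in the male and 86.3 CPM in the female library (log2 -0.84, interval -0.90 to -0.78). The histone demethylase genes Kdm6a and Kdm5c had ratios of -0.66 and -0.51, Pbdc1 of -0.58 and the helicase gene Ddx3x of -0.50. Of the non-coding genes beside Xist, Jpx was at -0.31 and Ftx at 0.02. Xist itself was at -13.82, and its antisense gene Tsix at -8.83, a value that is uncertain because both genes overlap. In all, 8 of the 9 measured members of the X inactivation and escape list were higher in the female library, with a list median of -0.58. The X chromosome as a whole did not stand apart, with a median of -0.03 over 406 X-linked genes outside the list and -0.03 over 11404 autosomal genes. Of these X-linked genes, 5 lay at or below -0.4: Slitrk4 at -0.76, Mid1 at -0.75, Agtr2 at -0.59, Cfp at -0.48 and Tab3 at -0.41. Another 5 lay at or above 0.4, and the autosomes had 116 and 215 genes beyond the same limits. Except for Agtr2, the 5 X-linked genes were named after their values were seen.

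Both libraries consisted mainly of mesenchyme-like cells, which made up 92.1% of male cells (8190; interval 91.5 to 92.6%) and 94.5% of female cells (9165; interval 94.0 to 94.9%). Endothelium-like cells made up 1.44% of male cells (interval 1.202 to 1.71%) and 0.773% of female cells (interval 0.609 to 0.968%). Epithelium-like cells made up 1.43% (1.19 to 1.70%) and 0.742% (0.581 to 0.934%), and immune-like cells 0.854% (0.674 to 1.07%) and 0.536% (0.401 to 0.702%). Erythroid-like cells were fewer in the male library, at 1.28% (1.06 to 1.54%) against 2.35% (2.06 to 2.67%). Glia and neural crest-like cells were at 0.483% (0.350 to 0.651%) and 0.567% (0.427 to 0.737%), and skeletal muscle-like cells at 0.360% (0.246 to 0.507%) and 0.546% (0.410 to 0.714%). All these shares are shares of the cells above 4854 UMIs, a limit that bears on small cells more than on large ones. With a limit of 2000 UMIs the immune-like shares were 0.340% and 0.213% and the erythroid-like shares 0.924% and 1.34%. The limit on genes removed a further 137 male and 193 female barcodes, each with over 50% of its UMIs from haemoglobin genes, and these are not in the erythroid-like share.

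A smooth muscle-like cluster was found in the male library almost alone, with 185 male cells (2.08%, interval 1.79 to 2.40%) and 1 female cell (0.0103%, interval 0.000261 to 0.0574%). The male share depended on the limits, at 1.14% with 500 UMIs, 1.20% with 2000 UMIs and 5.99% with at most 5% mitochondrial UMIs. The female share was 0% in each. With 1 library per group, a cluster mostly of 1 library may be that library, not a type. Its size was also taken from a clustering that left out the smooth muscle markers and the 10 leading genes of the cluster, an alternative chosen after seeing the data, in which the class held 182 male cells and 0 of 9701 female cells. This cannot tell a library from a type, because all other variable genes stayed in the clustering and the same markers gave the name. A count of 0 allows a share of up to 0.0309%. Without any clustering, 26 of 8895 male cells (0.292%, interval 0.191 to 0.428%) and 1 of 9701 female cells had at least 5 UMIs of the smooth muscle actin gene Actg2. For Acta2 the shares with at least 5 UMIs were 2.08% and 0.907%, and for Tagln 1.60% and 0.546%. The Acta2 shares are not shares of smooth muscle cells. Skeletal muscle-like cells held 1041 of 6322 male and 2016 of 3041 female Acta2 UMIs. For Cnn1 the shares with at least 5 UMIs were 0.0337% and 0.0206%, 3 and 2 cells, which does not separate the libraries. At least 1 Cnn1 UMI was seen in 93 male and 33 female cells. The name rests on 4 detected markers of 6, and the cartilage collagen gene Col9a1 was also among its 10 leading genes.

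**Figure D2:**
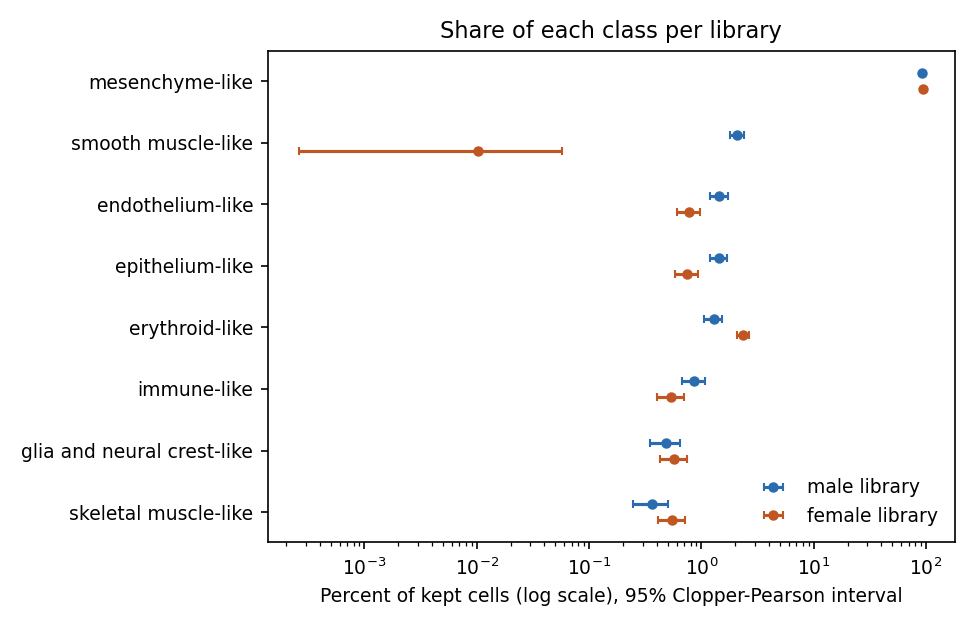
Percent of kept cells (log scale) in each of the 8 classes in the male and the female library, where points are shares and bars are 95% Clopper-Pearson intervals. The smooth muscle-like class lay at 2.08% in the male and 0.0103% in the female library, while the mesenchyme-like class lay at 92.1% and 94.5%.

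In mesenchyme-like cells, the transcriptomes of both sexes were close. The central 90% of the 12803 genes with a summed count of at least 100 lay between -0.27 and 0.31. Among the 12 highest ratios, male over female, were 4 histone genes, the ribosomal protein gene Rps6 and the smooth muscle actin gene Acta2. Among the 12 lowest were the transcription factor genes Sim1, Nr2f1, Foxp1 and Tshz3, the BMP antagonist gene Grem1 and the angiotensin receptor gene Agtr2. The 12 male-higher genes had a median ratio of 0.98 and the 12 female-higher genes a median of -0.57.

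Among the male-higher genes, the histone H2A gene Hist1h2ap (chromosome 13, 21833026 to 21833507) was at 197 CPM in the male and 64.0 CPM in the female library (log2 1.62, interval 1.57 to 1.67). Hist1h2ab was at 1.46, Hist1h2ae at 0.92 and the linker histone gene Hist1h1b at 0.75. These belong to a family of near-identical genes, so the split of reads among its members is uncertain. The lincRNA genes AY036118 (267 and 84.8 CPM, log2 1.65) and Gm42418 (2447 and 1191 CPM, log2 1.04) overlap on opposite strands, at 39847113 to 39848035 and 39846958 to 39848788 of chromosome 17. Both values are uncertain, and which transcripts their reads come from was not tested. Rps6, a protein of the small ribosomal subunit, was at 2661 and 1647 CPM (log2 0.69, interval 0.68 to 0.70). The lincRNA gene Gm10076 was at 0.86, a value that is uncertain where processed copies of ribosomal genes share their reads. Lars2, the mitochondrial leucyl-tRNA synthetase gene, was at 0.76. Gstp1, a glutathione transferase gene with a close paralogue, was at 27.0 and 13.0 CPM (log2 1.06).

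Acta2 (chromosome 19, 34241090 to 34255590) was at 25.5 CPM in the male and 12.3 CPM in the female mesenchyme-like cells (log2 1.05, interval 0.93 to 1.17). The ratio was not even across clusters of the class. It was 2.26 in cluster 3, led by Ogn and Rspo3, and 2.10 in cluster 16, led by Aldh1a2 and Tcf21, where the level was 306 CPM in the male and 71.1 CPM in the female library. It was -0.74 in cluster 5, led by Msx2 and Msx1, and -0.81 in cluster 12, led by Mab21l2 and Mecom. These clusters were singled out after their values were seen. Counted together with the smooth muscle-like cluster, the ratio of Acta2 was 2.62.

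Among the female-higher genes, Sim1 (chromosome 10, 50894754 to 50989152), a bHLH-PAS transcription factor gene, was at 20.4 CPM in the male and 34.9 CPM in the female library (log2 -0.78, interval -0.88 to -0.68). Grem1 (chromosome 2, 113746164 to 113758646) was at 23.9 and 39.6 CPM (log2 -0.73, interval -0.82 to -0.64). Agtr2 (chromosome X, 21484544 to 21489164), the type 2 receptor of angiotensin II, was at 15.7 and 23.7 CPM (log2 -0.59, interval -0.70 to -0.47). The orphan nuclear receptor gene Nr2f1 (chromosome 13, 78188973 to 78199757) was at 36.5 and 54.0 CPM (log2 -0.57, interval -0.64 to -0.49). Foxp1, a forkhead gene, was at 99.7 and 145 CPM (log2 -0.54). Enpp2, which encodes the lysophosphatidic acid-producing enzyme autotaxin, was at 74.8 and 108 CPM (log2 -0.53). The chromatin remodeller gene Chd7 was at -0.52, the neurofilament gene Nefm at -0.53, the N-myristoyltransferase gene Nmt1 at -0.57, Tshz3 at -0.51 and the lincRNA gene AC160336.1 at -0.65. Gm47283, annotated at 90784738 to 90816464 near the end of the Y chromosome, was at 33.3 and 72.3 CPM (log2 -1.12). It is uncertain, because a gene annotated on the Y chromosome had more counts in the female library. Sim1 and Agtr2 lead clusters 8 and 10, both also marked by Igf1 and Tbx15. Within these clusters Nr2f1 was at -1.14 and -0.92, Grem1 at -0.67 and -0.76, Sim1 at -0.55 and -0.65 and Agtr2 at -0.49 and -0.47. Other clusters went the other way, with Nr2f1 at 0.50 (interval 0.18 to 0.83) in cluster 16 and, with intervals that include 0, at 0.31 in cluster 15, Agtr2 at 0.69 in cluster 2, Sim1 at 0.43 in cluster 6 and Grem1 at 0.33 in cluster 2.

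All 24 genes had the same direction under all 15 alternatives computed for them (360 values). The genes were picked for extreme ratios, and the alternatives reuse largely the same counts, so a change of sign was unlikely from the start. Of the 12 male-higher genes, 11 were also above 0 in each of the other 4 classes compared, with Hist1h1b the exception, and 7 had intervals above 0 in each. Of the 12 female-higher genes, 8 were below 0 in each, but 1, Nr2f1, had intervals below 0 in each and 3 (Nmt1, Chd7 and Tshz3) in none. The erythroid-like class is not independent of the mesenchyme in this count, because its cells held mesenchyme markers at 40.7% (male) and 45.9% (female) of the mesenchyme-like level, and at 76.3% and 83.6% with haemoglobin left out. Epithelium-like cells held mesenchyme genes too, as given below. Some counts were small, such as 2 male and 2 female for Agtr2 in endothelium-like cells.

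**Figure D3:**
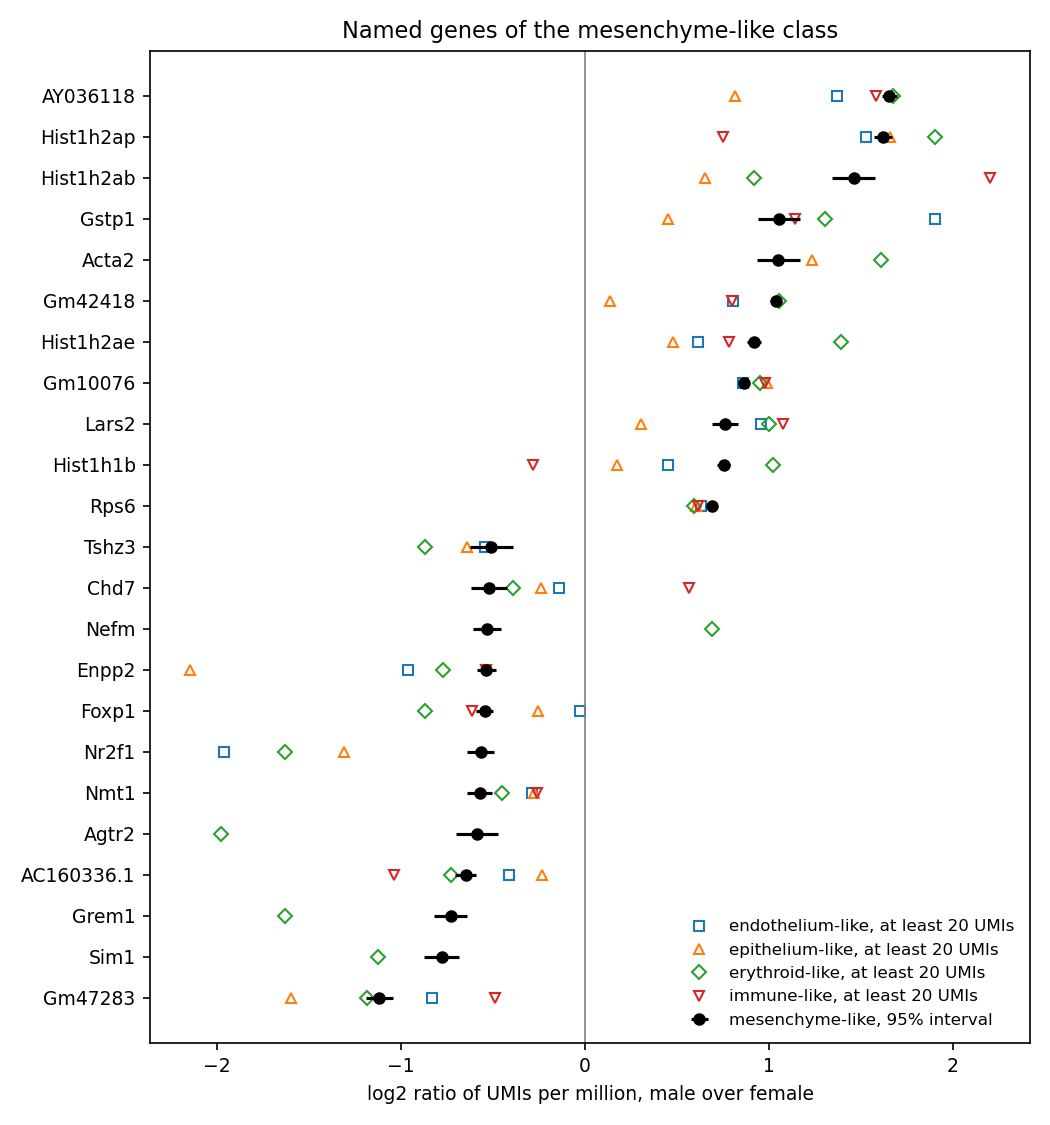
Log2 ratio of CPM, male over female, of 23 of the 24 genes named by rule in mesenchyme-like cells (black circles with 95% intervals for counting error) and in 4 other classes (open symbols, genes with at least 20 UMIs). Hist1h2ap lay at 1.62 in mesenchyme-like cells and between 0.75 and 1.90 in the other classes.

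The male and female pools were taken after the fetal testis begins to make androgen, so receptors and enzymes of steroid signalling were examined as a fixed list. Srd5a2, the enzyme that converts testosterone to dihydrotestosterone, was at 3.06 CPM in the male and 3.64 CPM in the female mesenchyme-like cells (log2 -0.25, interval -0.52 to 0.02), and its isozyme gene Srd5a1 at -0.11 (interval -0.27 to 0.05). The oestrogen receptor gene Esr1 was at 2.98 and 2.42 CPM (log2 0.30), a difference not detectable at this depth, because the interval includes 0. The glucocorticoid receptor gene Nr3c1 was at 0.19 (interval 0.06 to 0.32), but at -0.04 when cells were thinned to 2000 UMIs. Hsd17b4, a 17-beta-hydroxysteroid dehydrogenase gene, was at -0.05. Esr2, Pgr, Nr3c2 and Gper1 had under 100 counts in all, and Hsd17b3 and Cyp19a1 had 0 counts in both libraries. The 6 measured members had a median of -0.01, at percentile 57.2 of 10000 random lists matched on expression, and of 0.19 at percentile 97.8 with a minimum of 20 counts per gene.

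Of the 9 measured genes listed as androgen-responsive in the tubercle, 5 were higher in the male and 4 in the female mesenchyme-like cells, and 3 intervals lay above 0 and 3 below. Inhba, a subunit of activin, was at 77.8 and 69.4 CPM (log2 0.17) and Igf1, the insulin-like growth factor gene, at 81.7 and 76.9 CPM (log2 0.09). Fkbp5 was at 0.06, Ctsh at 0.12, Sfrp1 at -0.05, Tgfb2 at -0.07, Alx4 at -0.08 and Nedd4l at -0.12 (Alx4 was at 0.04 when thinned, and Sfrp1 was at 0.26 and Tgfb2 at 0.0016 with the smooth muscle-like cluster counted in), while Cyp1b1 had under 100 counts. The list median of 0.06 lay at percentile 97.7 of the random lists, and at percentile 83.8 with a minimum of 500 counts per gene. Percentiles describe these libraries only.

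Extracellular matrix genes were higher in the male mesenchyme-like cells for 16 of 20 members, with a median of 0.14 at percentile 100 of the random lists. Elastin (Eln) was at 10.4 and 7.35 CPM (log2 0.50, interval 0.34 to 0.67), the matricellular gene Postn at 32.4 and 23.5 CPM (log2 0.46), and the collagen genes Col1a1 and Col6a3 at 0.31 and 0.30. Genes of hypoxia and glycolysis were higher in the male library for 12 of 15 members (median 0.14, percentile 100), among them Ankrd37 at 0.42 and the glycolytic enzyme genes Eno1 and Pfkl at 0.30 each, with Ndrg1 at -0.36. BMP pathway genes were higher in the male library for 10 of 14 members (median 0.09, percentile 99.9). The inhibitory Smad gene Smad7 was at 0.32, the homeobox gene Msx2 at 0.23 and the decoy receptor gene Bambi at 0.20, while the antagonist gene Grem1 was at -0.73. With clusters of the class weighted alike in both libraries, the BMP median was 0.01, at percentile 82.2.

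All 9 ephrin and cell adhesion genes were higher in the female mesenchyme-like cells, with a median of -0.15 at percentile 1.93 (6.57 with equal cluster weights and 9.09 when thinned), among them Efna5 at -0.24, the N-cadherin gene Cdh2 and the Eph receptor gene Epha4 at -0.20 each and Ncam1 at -0.17. Hedgehog pathway genes had a median of -0.07 (percentile 24.2), with 9 of 12 higher in the female library, including the Hedgehog-binding protein gene Hhip at -0.29, Foxf2 at -0.24 and Gli3 at -0.12, and with the co-receptor gene Boc at 0.14. The Wnt list had 7 members higher in the male and 9 in the female library (median -0.04, percentile 41.0), with the R-spondin genes Rspo1 at 0.28 and Rspo3 at -0.29, Wnt6 at 0.38 and Dkk3 at 0.34. The FGF list had 4 and 8 (median -0.02, percentile 66.6), with Fgfr3 at 0.33, the feedback phosphatase gene Dusp6 at -0.30, Fgf10 at -0.24 and Fgf18 at -0.18. Hox and limb-type patterning genes had 6 and 12 (median -0.02, percentile 74.1), with Hoxd9 at 0.36, Tbx5 at -0.27 and Hoxa9 at -0.18. Retinoic acid genes had 5 and 7 (median -0.04, percentile 33.6), with the retinol transporter gene Stra6 at -0.35, Dhrs3 at 0.26, the synthesis enzyme gene Aldh1a2 at 0.17 and the receptor gene Rara at -0.17.

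Immediate early and heat shock genes, which can follow tissue dissociation, had a median of -0.03 in mesenchyme-like cells (percentile 46.3). There, 8 members were higher in the male and 10 in the female library. The endothelium-like median was -0.30 (percentile 0), with 16 of 17 members higher in the female library. The erythroid-like median was -0.27 (percentile 1.16), the immune-like -0.12 (percentile 11.4) and the epithelium-like -0.02 (percentile 78.4). In mesenchyme-like cells, Fosb was at 4.79 and 2.11 CPM (log2 1.18, interval 0.90 to 1.47), Junb at 0.30, Hsph1 at -0.35 and Atf3 at -0.35, which was at 0.32 with the smooth muscle-like cluster counted in. The haemoglobin list had a median of 0.02 (percentile 75.2) with members in both directions, Hbb-bs at 0.63 and Hbb-bt at 0.45 against Hbb-bh1 at -0.85 and Hba-x at -0.45. Both Hbb-bs and Hbb-bt lay below 0 in some alternatives, and Hbb-bs was at 4.10 after free RNA was subtracted. Genes of the surface epithelium, counted in mesenchyme-like cells, had a median of 0.54 at percentile 99.98 (7 of 7 measured members higher in the male library), alongside the larger share of epithelium-like cells in that library.

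**Figure D4:**
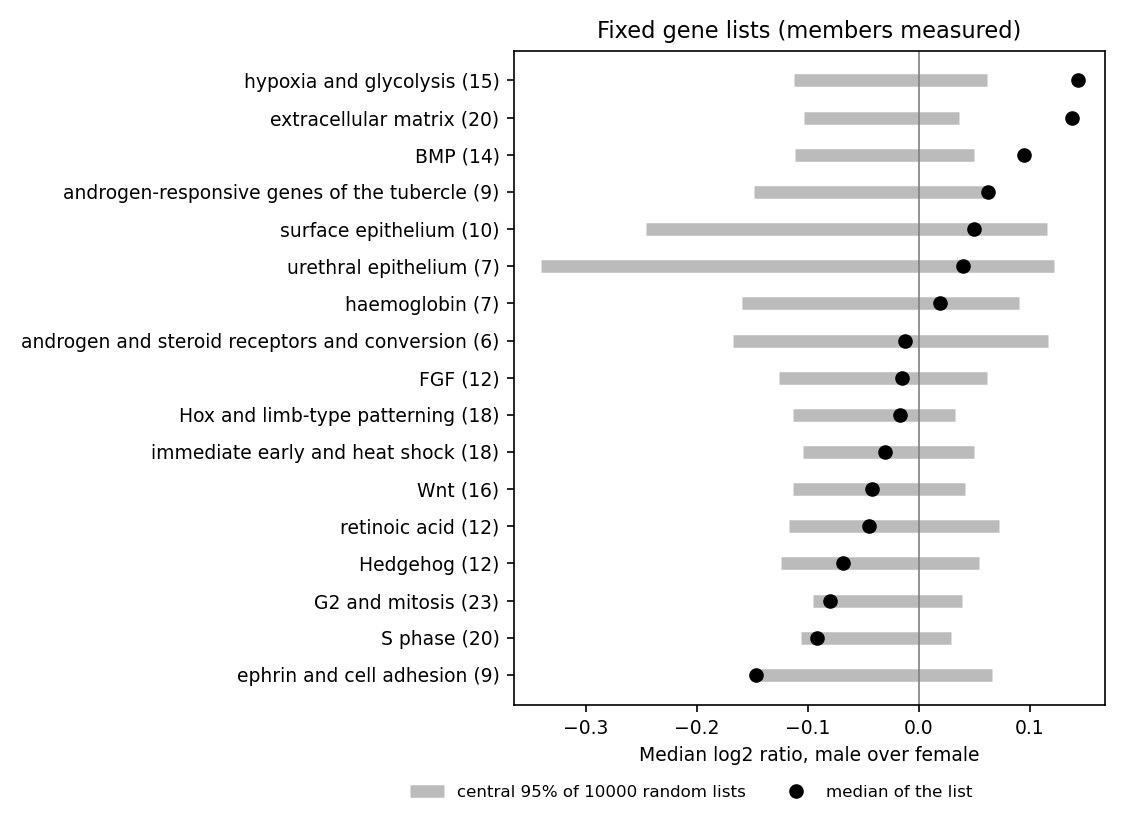
Median log2 ratio, male over female, of each fixed gene list (points, with the number of measured members), in mesenchyme-like cells except for the 2 epithelium lists, which are shown in epithelium-like cells. Grey bars are the central 95% of 10000 random lists matched on expression, and the extracellular matrix list at 0.14 and the ephrin and cell adhesion list at -0.15 lie outside them, the latter not with equal cluster weights or when thinned.

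In endothelium-like cells (128 male and 75 female), the blood vessel class, the largest male-higher values were those of matrix genes and rested on 3 cells. Eln had 441 male and 0 female counts (at least 75.6-fold higher), Fbln5 230 and 2 counts (log2 5.89, interval 4.02 to 8.94) and Fbln2 151 and 9 counts (log2 3.11). Without the 3 cells with at least 2 Eln UMIs, Eln had 1 and 0 counts, Fbln5 was at 0.89 (interval -1.50 to 4.19) and Fbln2 at 0.91 (interval -0.19 to 2.16). Ctsh, a lysosomal protease gene, was at 2.38 with and 1.36 without them, and Hist1h2ap at 1.53 with them. In the female library, Id1, a BMP target gene, was at 835 against 429 CPM (log2 -0.96, interval -1.08 to -0.84) and the hormone gene Stc1 at -0.93. The embryonic globin genes Hbb-y and Hba-x were at -2.16 and -1.19 and Hba-a1 at -1.13, but for each gene 1 female cell held most female counts, and without it the values were 1.86, 3.88 and 2.16. These counts without the cell that holds most UMIs of a gene were made after the values were seen, and of 40 values named by rule in the 4 smaller classes, 11 changed sign, all of globin genes.

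In epithelium-like cells (127 male and 72 female), Krt15, a keratin of basal cells, was at 719 CPM in the male and 412 CPM in the female library (log2 0.80, interval 0.64 to 0.97). Krtdap was also at 0.80 and the hemidesmosome collagen gene Col17a1 at 0.67, while Krt17 was at -0.23. The surface epithelium list had 7 of 10 members higher in the male library (median 0.05, percentile 89.1). The urethral epithelium list had 5 of 7 (median 0.04, percentile 88.5), with Krt18 at 0.14, Cldn7 at 0.09 and the lower values of Krt19 and the claudin gene Cldn4 at -0.48 each. Krtdap, Krt19 and Lef1 changed direction when cells were thinned to 2000 UMIs, to -0.33, 0.27 and 0.64. Female-higher genes were the homeobox gene Zfhx4 at -1.54, Rprm at -1.52, the Wnt effector gene Lef1 at -1.37 and the retinoic acid-binding protein gene Crabp2 at -1.36, with the uncertain Gm47283 at -1.60. The mesenchyme genes Isl1 and Msx1 were also higher in female epithelium-like cells, as given below. Male-higher genes were Hist1h2ap at 1.66 and the globin genes Hbb-bs at 2.97, Hbb-bt at 2.00, Hba-a2 at 1.36 and Hba-a1 at 1.26. The globin values rested on 1 male cell per gene and turned without it, to -0.42, -0.31, -0.98 and -0.47, as they did with 16% of cells removed as doublets.

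In erythroid-like cells (114 male and 228 female), the male-higher genes were also male-higher in mesenchyme-like cells, among them Hist1h2ap at 1.90, AY036118 at 1.67, Hist1h2ae at 1.39 and Gm42418 at 1.05. Female-higher were Spats2l at -1.06 and the mitotic genes Kif20b, Cdca3 and Cenpe at -0.98, -0.96 and -0.88, with Foxp1 at -0.87. With a limit of 2000 UMIs the 3 mitotic genes were at 0.14, -0.14 and -0.06. These cells held a median of 42.1% (male) and 45.9% (female) haemoglobin UMIs together with mesenchyme transcripts such as Isl1, at 171 and 208 CPM, so that they mix RNA of both kinds. The median of all genes in this class, -0.09, moved to 0.02 with median-of-ratios scaling and to 0.09 with a limit of 2000 UMIs.

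In immune-like cells (76 male and 52 female), mast cell protease genes were higher in the male library. Mcpt2 had 295 and 0 counts (at least 67.8-fold higher) and Mcpt1 164 and 0 counts (at least 37.7-fold higher), carried by 6 and 2 cells, and Mcpt4 was at 4.12, with UMIs in 8 male cells and 1 female cell. Tph1, the tryptophan hydroxylase gene that mast cells use to make serotonin, was at 3.96, with 82.2% of its counts in 3 cells. The interferon-induced chemokine gene Cxcl10 was at 286 and 62.8 CPM (log2 2.19), and at 0.51 (interval -0.05 to 1.09) without the 1 male cell that held 59.9% of its counts. The mast cell genes Cpa3 and Cma1 were looked at after these values were seen. Cpa3 had UMIs in 22 male and 10 female cells and was at 0.65, and Cma1 was at 1.97. Female-higher were globin genes, from Hba-a2 at -2.57, Hba-x at -2.49 and Hbb-bs at -2.45 to Hba-a1 at -1.75 and Hbb-bt at -1.73, but 1 female cell held from 57.8% to 76.7% of the counts of each. Without it Hbb-bs was at -0.23 (interval -0.80 to 0.35) and the others turned, to 1.86 for Hba-a2, 1.66 for Hba-x, 2.56 for Hba-a1 and 0.80 for Hbb-bt, and at 20% mitochondrial UMIs these 4 were above 0 as well.

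Most genes of cell division were slightly lower in the male mesenchyme-like cells. With each cell thinned to 2000 UMIs, which left out no cell, a UMI of the proliferation marker gene Mki67 was seen in 27.3% of male cells (interval 26.3 to 28.2%) and 30.5% of female cells (interval 29.5 to 31.4%). Unthinned, the shares were 49.6% and 55.7%. With a limit of 500 UMIs for cells and the same thinning to 2000 UMIs, they were 17.8% and 21.1%. The shares thus depended on the limit for cells, while the female share stayed higher. No class that should lack Mki67 was fixed, and the lowest thinned share was 12%, in female endothelium-like cells, whose median depth was 14504 UMIs against 6989 UMIs in female mesenchyme-like cells. Thinned shares in the other classes were 20.3% in male endothelium-like cells, 18.1% and 30.6% in epithelium-like cells, 17.5% and 16.2% in erythroid-like cells and 32.9% and 32.7% in immune-like cells. S phase genes made up 0.286% of male and 0.299% of female mesenchyme-like UMIs and G2 and mitosis genes 0.684% and 0.704%. In the S phase list 15 of 20 members were higher in the female library (median -0.09, percentile 5.71), with Cdc6 at -0.22 and the replication helicase genes Mcm4 and Mcm2 at -0.16 and -0.15, and with Gins2 at 0.16. In the G2 and mitosis list it was 16 of 23 (median -0.08, percentile 6.16), with the centromere protein genes Cenpe and Cenpf at -0.25 and -0.20 and the spindle genes Bub1b and Tpx2 at -0.20 each. With equal cluster weights the median of the latter list was 0.01.

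The classes differed in which ligands and receptors they held, compared over 7 classes without the smooth muscle-like one, which had 1 female cell. Some genes had a higher level in the male smooth muscle-like cells than in any of the 7, such as Bmp5 at 17.3 CPM. Shh, the signal of the urethral plate, was at 69.7 CPM in male and 67.8 CPM in female epithelium-like cells. Its receptor gene Ptch1 was highest in mesenchyme-like cells (164 and 174 CPM), as were its targets Gli1 (26.3 and 25.9 CPM) and Foxf1 (41.1 and 43.2 CPM). Of the Hedgehog genes, 9 of 13 had the same highest class in both libraries, 7 of them in mesenchyme-like and 2 in epithelium-like cells. Wnt4 (475 and 384 CPM), Wnt6 (285 and 253 CPM) and Wnt7b (142 and 113 CPM) were highest in epithelium-like cells, whereas Wnt5a (334 and 349 CPM) was highest in mesenchyme-like cells. For the Wnt list the same class was highest in both libraries for 18 of 20 genes, for the FGF list for 10 of 14 and for the BMP list for 11 of 14. Fgfr2 was epithelial (149 and 118 CPM) and Fgfr1 mesenchymal (148 and 149 CPM), while the FGF feedback genes Dusp6 (155 and 196 CPM) and Spry1 (135 and 188 CPM) were highest in endothelium-like cells. The distal limb and tubercle genes Hoxd13 (162 and 180 CPM) and Hoxa13 (88.7 and 84.9 CPM), Isl1 (434 and 477 CPM) and Msx1 (344 and 338 CPM) were highest in mesenchyme-like cells, and all 18 Hox and limb-type patterning genes had the same highest class in both libraries. For the retinoic acid list this held for 7 of 14 genes.

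**Figure D5:**
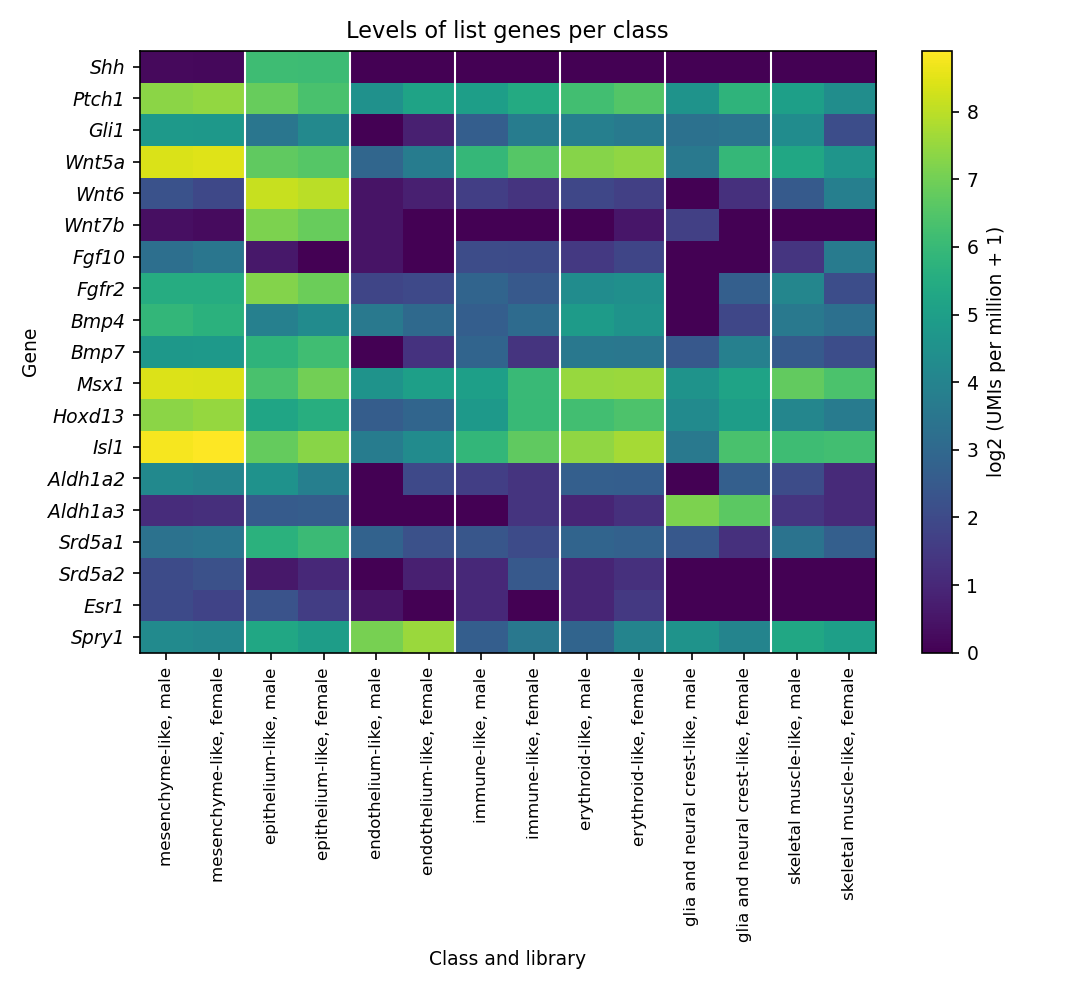
Colour shows log2 (CPM + 1) of 19 members of the fixed lists in 7 classes of the male and the female library. Shh lay at 69.7 (male) and 67.8 (female) CPM in epithelium-like cells, and Hoxd13 at 162 and 180 CPM in mesenchyme-like cells.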

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

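None of the values in this part comes from a test, and the comparisons between classes were looked at only after the values were seen. Barcodes with under 100 UMIs, which are not cells, held haemoglobin UMIs at 2.18% of their total in the male library and 2.72% in the female library. They were used only to estimate and subtract free RNA, so this is a signal in data outside the main comparisons. Barcodes with at least 1000 UMIs but below the limit for cells numbered 9717 in the male and 10023 in the female library. They entered comparisons only under alternatives with a lower limit on UMIs.

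Haemoglobin genes had opposite directions in 2 classes, which drew attention, and the difference between the classes was not tested. Hba-a1 was at 1.26 in epithelium-like and -1.75 in immune-like cells, Hba-a2 at 1.36 and -2.57, Hbb-bs at 2.97 and -2.45 and Hbb-bt at 2.00 and -1.73 (log2, male over female). A single cell per gene and class carried most of these counts. Without it the epithelium-like values were -0.47, -0.98, -0.42 and -0.31 and the immune-like values 2.56, 1.86, -0.23 and 0.80, in the same order of genes, so no direction within a class held without a single cell, Hbb-bs in immune-like cells included (interval -0.80 to 0.35).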

How the results depend on the processing

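The removal of the 16% of cells with the highest doublet scores, the 20% mitochondrial limit for levels, the smooth muscle-like cluster counted with the mesenchyme and the clustering without smooth muscle genes were chosen after seeing the data, while the other alternatives were planned. No paired analysis was possible because both labels carry the replicate number 1 only and the results come from no test. Of 2145 values of 151 named gene results under 15 alternatives, 1892 stayed within the counting interval, 225 moved out of it and 28, of genes whose interval excluded 0, changed sign. Of 115 list medians under 7 alternatives, 112 moved by no more than the distance from the middle to the edge of the central 95% of random lists. Each of the 8 classes kept its direction between libraries under all alternatives that gave it a value (13, or 12 for the glia and neural crest-like class, which no cluster was named for at 5% mitochondrial UMIs). Except where the construction of an alternative is named, the cause was not tested. Depth limited how many genes could be compared, since 2294 genes reached 100 counts in immune-like cells against 12803 in mesenchyme-like cells. No value came from equal cluster weights outside the mesenchyme-like class, for gene levels of the immune-like class at 2000 UMIs or with 16% of cells removed, from the urethral epithelium list at a minimum of 500 counts, or from the haemoglobin list after free RNA was subtracted. Subtraction and thinning also left some single genes without a value.

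With a limit of 500 UMIs, 16072 male and 17995 female cells were kept, and with 2000 UMIs 15587 and 15977. Lower limits admit more cells by construction. At 500 UMIs the shares were 93.1% and 94.9% for mesenchyme-like cells, 1.14% and 0% for smooth muscle-like, 0.865% and 1.41% for erythroid-like, 0.510% and 0.383% for immune-like, 0.243% and 0.372% for glia and neural crest-like, and 0.187% and 0.339% for skeletal muscle-like cells, and 1.03% for male endothelium-like cells. At 2000 UMIs they were 94.996% and 96.7% for mesenchyme-like, 1.1997% and 0% for smooth muscle-like, 0.930% and 0.501% for endothelium-like, 1.02% and 0.570% for epithelium-like, 0.924% and 1.34% for erythroid-like, 0.340% and 0.213% for immune-like, 0.263% and 0.325% for glia and neural crest-like, and 0.186% and 0.338% for skeletal muscle-like cells. The Y-linked genes were at 173 CPM in the male library at both limits (173.5 and 173.1), and Xist was at 1323 and 1328 CPM in the female library, and at 1295 CPM when thinned to 2000 UMIs. Mki67 was seen in 17.8% and 21.1% of mesenchyme-like cells at a limit of 500 UMIs, also thinned to 2000 UMIs. That thinning left out 395 male and 416 female cells with fewer UMIs. At the main limit the shares were 16.4% and 18.1% when thinned to 1000 UMIs and 49.6% and 55.7% unthinned. By Mki67 UMIs in place of the summed S phase or G2 and mitosis lists, the ratio was -0.19.

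With at most 5% mitochondrial UMIs, 785 male and 767 female cells were kept. The shares were then 80.0% and 81.5% for mesenchyme-like, 5.99% and 0% for smooth muscle-like, 2.55% and 2.09% for epithelium-like, 6.37% and 11.6% for erythroid-like and 2.29% and 2.87% for skeletal muscle-like cells, and 0.782% for female immune-like cells. Without doublet removal endothelium-like cells made up 1.72% and 1.00%. With 16% removed as doublets immune-like cells made up 0.519% and 0.314%. The female smooth muscle-like share was 0% with 16% removed, with 4000 variable genes and without the smooth muscle genes in the clustering.

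Reversed haemoglobin values in mesenchyme-like cells were Hbb-bs at -0.47 (500 UMIs), -0.23 (no doublet removal) and -0.0210 (16% removed), and Hbb-bt at -0.45 (500 UMIs), -0.0479 (2000 UMIs), -0.37 (no doublet removal), -0.17 (16% removed) and -0.0922 (20% mitochondrial UMIs). In epithelium-like cells with 16% removed, Hba-a1 was at -0.25, Hba-a2 at -1.20, Hbb-bs at -0.46 and Hbb-bt at -0.36. In immune-like cells at 20% mitochondrial UMIs, Hba-a1 was at 2.56, Hba-a2 at 1.69, Hba-x at 1.50 and Hbb-bt at 0.78. In endothelium-like cells Hba-a1 was at 0.20 thinned and 0.79 by the mean of cells. Outside the globins, thinning to 2000 UMIs reversed Krt19 (0.27), Krtdap (-0.33) and Lef1 (0.64) in epithelium-like and Alx4 (0.0379) and Nr3c1 (-0.0382) in mesenchyme-like cells, and the mean of cells reversed Krt19 (0.20) and Krtdap (-0.0944). Kif20b in erythroid-like cells was at 0.14 with a limit of 2000 UMIs. With the smooth muscle-like cluster counted in, Atf3 was at 0.32 and Tgfb2 at 0.0016. The haemoglobin list median was -0.12 when thinned, the steroid list median 0.19 (percentile 97.8) with a minimum of 20 counts, which admits more genes, and the G2 and mitosis median 0.0121 with equal cluster weights. The median of all genes in erythroid-like cells was 0.0156 with median-of-ratios scaling and 0.0872 with a limit of 2000 UMIs.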

Other observations

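The tests of explanations in this part were all chosen only after the results they bear on had been seen. The cells of the smooth muscle-like cluster differed from male mesenchyme-like cells in patterning genes that did not name the cluster. The endodermal and mesodermal transcription factor gene Gata6 was higher in the cluster (log2 3.24, cluster over male mesenchyme-like cells). The posterior Hox genes Hoxd13 and Hoxa13 were lower (-1.94 and -1.25), as were Isl1 (-1.89) and the limb-type gene Tbx5 (-1.78). The proliferation gene Mki67 was at -1.54. Markers of smooth muscle were not raised alike, with Myh11 at -0.16 (interval -0.98 to 0.55), Synpo2 at -1.75 and Des at 1.71 (interval 1.11 to 2.25). These genes were chosen after their values were seen.

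In epithelium-like cells, 20 of 22 measured G2 and mitosis genes were higher in the female library (median -0.36, against -0.09 for all genes, percentile 0 of the random lists), and the Mki67 shares lay in the same order. Endothelium-like cells went the other way, with 19 of 23 members higher in the male library (median 0.20, percentile 99.99). The erythroid-like median was -0.36 and the immune-like -0.19. Extracellular matrix genes of the epithelium-like cells had a median of -0.41 (percentile 0.28), with 7 of 8 members higher in the female library, the opposite direction to the mesenchyme-like class. Mesenchyme genes lay in the same order in epithelium-like cells, with Isl1 at 109 and 160 CPM and Msx1 at 81.3 and 128 CPM in the male and female library. The Hedgehog list had a median of 0.20 (4 of 4 members higher in the male library, percentile 98.9) and the Wnt list of 0.17 (5 of 8, percentile 99.2), in spite of Lef1 at -1.37 (0.64 when thinned to 2000 UMIs). The epithelium-like values rest on 127 male and 72 female cells of 1 library each.

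The male-higher genes of the mesenchyme-like class were mostly also higher in the male library elsewhere. Of the 12 genes, 11 had a ratio above 0 in each of the other 4 classes compared, and 7 had intervals above 0 in each, so a candidate explanation is a difference between the libraries as a whole rather than in the mesenchyme. More cells in S phase is argued against as the cause of the histone values, because the S phase list had a median of -0.0919 while the 4 histone genes had a median of 1.19. Free RNA stays open. The median of the 12 genes was 0.90 after the background profile was subtracted, against 0.98 before. That profile came only from barcodes with under 100 UMIs (1181377 male barcodes with 2431208 UMIs in all). It left out barcodes just above this limit, such as male rank 51478 at 126 UMIs and female rank 51350 at 128 UMIs, so the subtraction cannot decide. How the samples were handled and prepared, and sex itself, stay open and untested, because each sex is 1 library.

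For the smooth muscle-like cells of the male library, a candidate explanation is tissue from beside the tubercle that entered the male pool. The posterior Hox genes leave this open, because all 16 mesenchyme-like clusters had a Hoxd13 level above that of the cluster, but 13 had both Hoxd13 and Hoxa13 above it. Doublets between cells of other clusters are argued against, because random pairs from any other clusters would have given at least 59.5 female cells beside the 185 male ones, while 1 was found, although removal of the 16% of cells with the highest doublet scores took 13.5% of these male cells and 8.75% of the male mesenchyme-like cells. Effects of sex, a response to androgen among them, stay open and untested.

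The female-higher genes of the mesenchyme-like class, among them Sim1, Grem1, Agtr2 and Nr2f1, could reflect unlike mixtures of mesenchyme or unlike depth. With equal cluster weights in both libraries their median was -0.56, against -0.57 before, and at 2000 UMIs per cell it was -0.63. Neither the shares of the clusters nor depth therefore accounts for the median of the 12 genes. Single genes moved more: over all alternatives Sim1 lay between -0.85 and -0.57 and Agtr2 between -0.72 and -0.38. For Grem1 the range was -0.77 to -0.59 and for Nr2f1 -0.62 to -0.52. Unlike mixtures within a cluster stay open, because the weights do not act on them. A difference between the libraries as a whole was not excluded, since 8 of the 12 genes were below 0 in each of the other 4 classes, though of the 12, 1 had intervals below 0 in each and 3 in none. This count cannot decide, because other classes held mesenchyme RNA too, with Isl1 and Msx1 higher in female epithelium-like cells. Some counts were also small, such as 2 male and 2 female for Agtr2 in endothelium-like cells. Sex and the particular embryos pooled stay open and untested.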
